A study of Mus musculus with 13 samples.

How the data were processed

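The data are bulk RNA sequencing of 13 mouse samples that the labels place in 3 groups: FAPs of skeletal muscle (4 libraries, replicates 2 to 5), FAPs of lung (5 libraries, replicates 1 to 5) and MEFs (4 libraries, replicates 1 to 4). FAP is used in the field for fibro/adipogenic progenitor and MEF for mouse embryonic fibroblast, and the labels give the abbreviations alone. Total RNA was extracted with Trizol and a column kit and prepared with an Illumina kit, per the labels' protocols. The sort or gate by which FAPs were taken, the sex of the animals, sequencing batches, the strand of the libraries and the gene annotation are not given in the sources used here. Reads were aligned to mm10 with Bowtie2 2.1.0.0 and counted with HTSeq, per the submitters' processing notes, which also name edgeR and give no version for HTSeq or edgeR. The deposited table holds 1 read count per gene and library, for 23418 genes and with 0 columns of other samples. The labels do not say that the replicates come from separate animals or cultures.

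Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 as a quasi-likelihood negative binomial model with robust dispersion, with all 13 libraries in 1 fit and group as the only factor. Genes were kept by filterByExpr, given the groups, which left 15412 genes. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. The comparisons are muscle FAP against lung FAP, muscle FAP against MEF and lung FAP against MEF, and the genes that passed in the same direction for muscle FAP against both other groups. Levels are given as CPM scaled by TMM, mean ± SD over the libraries of a group. The SE of a log2 fold change was taken from the libraries' log2 CPM with a prior count of 2. Where a group had no count for a gene, a fold is given as at least its ratio to 3 counts over the whole group. Where a group had 1 to 3 counts, a ratio is given with its exact 95% counting interval. These floors and intervals cover counting error only.

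The lists of genes held 474 members in 25 lists, of which 470 were in the table. C5, Muc16, Hbb-bs and Hbb-bt were not found under those symbols. The first 14 lists cover mesenchymal progenitor markers, extracellular matrix, growth factors, antagonists of WNT, BMP and activin, cytokines and chemokines, complement, adipogenic genes, contractile and myofibroblast genes, transcription factors of limb mesenchyme, genes of lung mesenchyme, Hox paralogs 1 to 8, Hox paralogs 9 to 13, the cell cycle, and the immediate-early and stress response. The other 11 lists hold markers of satellite cells and myoblasts, muscle fibres, lung epithelium, blood cells, endothelium, pericytes and smooth muscle, mesothelium, tenocytes, Schwann cells, red blood cells and sex. Each list was tested with camera in limma 3.58.1 on log2 CPM, at a preset correlation between genes of 0.01. Each was tested again with the correlation estimated from the data, and with fry.

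The genes named in the text follow a rule set before the data were examined. In each comparison it takes the 4 largest log2 fold changes in each direction among passing genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups, and it passes over predicted symbols. From each of the 14 lists it takes the 2 passing members with the largest log2 fold change and at least 5 CPM in the higher group in muscle FAP against lung FAP, and 1 such member in the other comparisons. From each of the other 11 lists it takes the member with the highest mean CPM, passing or not. It adds Pdgfra and Ly6a, and the 6 signalling genes highest in muscle FAP against both other groups. Further members of the lists are given as examples, and some genes that the rule takes are not reported here. The groups, the comparisons, the lists, this rule and the alternatives named next were chosen before the data were examined.

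The alternatives were size factors of DESeq2 1.42.0 in place of TMM, upper-quartile scaling, no filter on expression, a filter of at least 5 CPM in at least 4 libraries, the Wald test of DESeq2, limma-voom with sample weights, edgeR's glmTreat against a 2-fold change, the libraries of the compared groups alone, the replicate number as a block, and each library left out in turn. Scaling by library size only, and leaving out lung FAP 2 and 3, lung FAP 2, 3 and 4, or MEF 2 and 4, were chosen after seeing the data.

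The libraries held 41327292 to 44699463 counts in muscle FAPs, 28636183 to 35464622 in lung FAPs and 33756915 to 41466585 in MEFs, so 3 counts over a group correspond to 0.0219, 0.0178 and 0.0168 CPM. The edgeR fit was tested on simulated data with known changes in few genes and the libraries' own depth and spread. It recovered 31.3%, 55.4% and 80.7% of changes of 1.5-fold, 2-fold and 4-fold for muscle FAP against lung FAP. The shares were 14.5%, 60.9% and 82.8% for muscle FAP against MEF, and 19.7%, 53.9% and 69.7% for lung FAP against MEF. Of the simulated genes called, 0.935%, 2.89% and 4.08% had no change. For muscle FAP against lung FAP, 64, 65 and 62 of 14677 simulated genes changed by these folds. In the data 48.2% of genes passed in that comparison, and 73.5% and 74.4% in those with MEF. Adjusted p values depend on the share of changed genes, so the recovered and false shares need not hold for the data. The positions and shared sequence of the named genes were taken from GENCODE M21 on GRCm38, the assembly of mm10.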

Results

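The series asks which signals of skeletal muscle act on satellite cells, the stem cells of muscle fibres, and sequenced FAPs of muscle and of lung together with MEFs. Its parabiosis experiments are not analysed here. The libraries separated by group first. The first principal component held 64.9% of the variance and set MEFs apart from both kinds of FAP, and the second held 20.9% and set muscle FAPs apart from lung FAPs. Spearman correlations of log2 CPM were 0.988 to 0.994 among muscle FAPs, 0.964 to 0.985 among lung FAPs and 0.986 to 0.997 among MEFs. Between groups they were 0.905 to 0.936 for muscle FAPs and lung FAPs, 0.780 to 0.795 for muscle FAPs and MEFs, and 0.764 to 0.786 for lung FAPs and MEFs. Values below are mean ± SD in CPM, with n = 4 for muscle FAPs, n = 5 for lung FAPs and n = 4 for MEFs throughout. Since the labels do not say that replicates come from separate animals or cultures, the p-values measure the spread between these samples, which may be technical in part. MEF 1 and MEF 2 do not hold the same cells, with Xist at 0.123 and 88.5 CPM and Ddx3y at 70.9 and 0.0646.

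**Figure D1:**
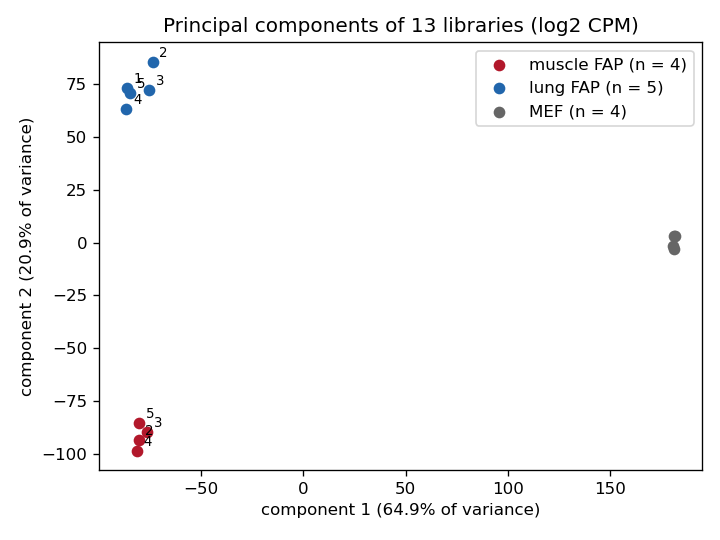
First and second principal components (percent of variance on each axis) of log2 CPM for 13 libraries, where each point is a library, with replicate numbers beside the FAPs. Component 1 (64.9%) separates MEFs from FAPs and component 2 (20.9%) separates muscle FAPs from lung FAPs.

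Pdgfra and Ly6a encode the surface receptor and the stem cell antigen by which FAPs are defined in the field. Pdgfra stood at 1384 ± 91.4 CPM in muscle FAPs, 792 ± 27.5 in lung FAPs and 29.8 ± 4.88 in MEFs. It was 1.75-fold higher in muscle FAPs than in lung FAPs (edgeR log2 fold change 0.80, SE 0.053, adjusted p = 4.98e-05), and 46.4-fold (adjusted p = 2.04e-13) and 26.6-fold (adjusted p = 4.58e-13) above MEFs in the muscle and lung groups. Ly6a stood at 772 ± 158, 846 ± 199 and 87.95 ± 23.2 CPM and did not differ between both kinds of FAP (log2 fold change −0.14, SE 0.20, edgeR adjusted p = 0.601). With library size as the only scaling that value was −0.54 (edgeR adjusted p = 0.0286). Against MEFs Ly6a was 8.78-fold higher in muscle FAPs (edgeR adjusted p = 8.38e-09) and 9.62-fold higher in lung FAPs (adjusted p = 4.24e-09). Cd34, another surface marker of FAPs, stood at 1619 CPM in muscle FAPs, 1625 in lung FAPs and 24.9 in MEFs.

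Muscle FAPs and lung FAPs differed strongly in genes that record position along the body. Hoxc10, a homeobox transcription factor of the posterior trunk and hindlimb, stood at 31.9 ± 3.14 CPM in muscle FAPs and had no count in any lung FAP, a difference of at least 1790.1-fold (edgeR adjusted p = 2.29e-10). Hoxa10 stood at 18.5 ± 1.197 against 0.0298 ± 0.0201 CPM, 621-fold higher (adjusted p = 3.40e-12 in edgeR). Hoxa9 stood at 6.51 ± 1.02 CPM against no count, at least 365-fold (edgeR adjusted p = 1.39e-08). En1, a homeobox gene of ventral limb skin and midbrain, had 11.7 ± 1.21 CPM in muscle FAPs and 2 reads over all lung FAPs, a ratio of 990.0 (95% interval 274 to 8182) with an edgeR adjusted p of 3.16e-11. Grm8, a metabotropic glutamate receptor, stood at 12.8 ± 3.21 CPM against no count, at least 717-fold (edgeR adjusted p = 1.38e-08). Of 16 tested Hox genes of paralogs 9 to 13, 13 were higher in muscle FAPs, 0 were lower and 3 did not pass. Their median log2 fold change was 5.43. It was 6.32 with genes without counts at their bound and genes of at most 3 counts in both groups left out. Medians at the bounds below follow the same rule. The camera adjusted p of that list was 4.55e-09, and its adjusted p = 0.0141 with an estimated correlation. Of 21 Hox genes of paralogs 1 to 8, 8 were higher, 9 lower and 4 did not pass (camera adjusted p = 0.63). Hoxc8 rose by 6.44 (SE 0.59, edgeR adjusted p = 5.01e-07; 7.09 without lung FAP 5) and Hoxc6 by 4.88 (SE 0.80, adjusted p = 4.10e-06), while Hoxb4 (−2.46) and Hoxb5 (−3.52) fell.

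Transcription factors of limb mesenchyme and genes of lung mesenchyme moved in opposite directions between both kinds of FAP. Tbx15, a T-box factor of limb and trunk mesenchyme, stood at 179 ± 50.02 CPM in muscle FAPs and 0.723 ± 0.542 in lung FAPs (log2 fold change 7.94, SE 0.88, edgeR adjusted p = 6.61e-08). Shox2, which shapes the proximal limb skeleton, stood at 17.3 ± 5.25 against 0.419 ± 0.445 CPM (5.36, SE 0.76, edgeR adjusted p = 6.19e-06; 6.21 without lung FAP 5). The list of limb factors held 11 higher genes, 1 lower gene and 4 that did not pass (camera adjusted p = 0.000223; adjusted p = 0.11 with an estimated correlation), with Meox1 (2.85) among the higher and Twist2 (−0.55) the lower. All 13 genes of lung mesenchyme were lower in muscle FAPs (camera adjusted p = 9.55e-09; adjusted p = 0.11 with an estimated correlation). Tcf21, a transcription factor of lung fibroblasts, stood at 0.759 ± 0.656 CPM in muscle FAPs against 112 ± 13.1 in lung FAPs (−7.21, SE 0.79, edgeR adjusted p = 8.84e-08). Npnt, an integrin ligand of the alveolar wall, stood at 1.18 ± 0.309 against 231 ± 137 CPM (−7.61, SE 0.40, edgeR adjusted p = 4.47e-08). Foxf1 fell by 3.87 and Tbx4 by 2.66. The sum of the lung list was highest in lung FAP 2, at 6260 CPM, with 3690 to 4399 in the other lung FAPs and 872 to 1257 in muscle FAPs. Lung FAP 2 was also the lung library with the highest endothelial and pericyte sums.

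**Figure D2:**
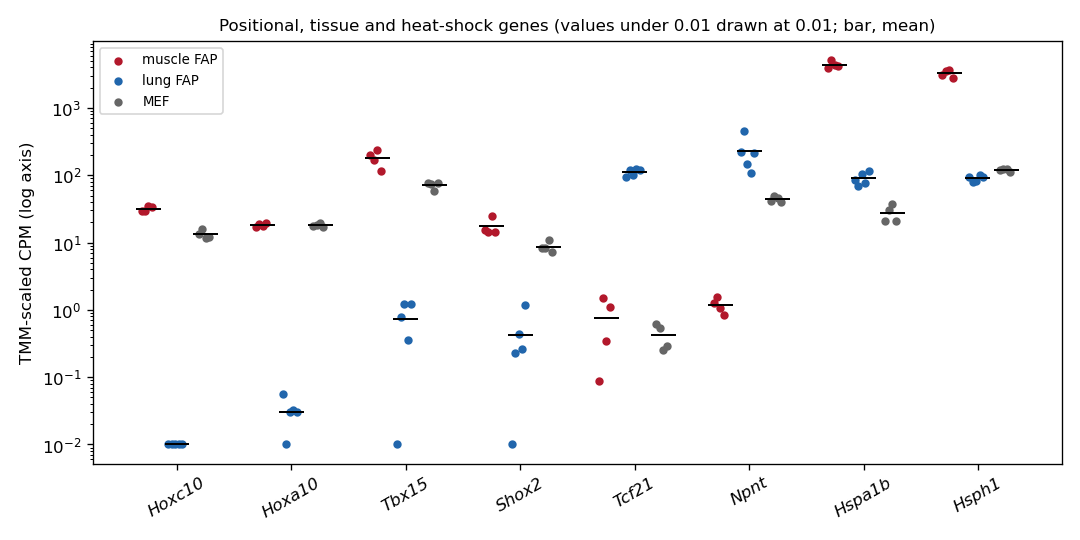
TMM-scaled CPM (log axis) of 8 genes of body position, tissue and heat shock in muscle FAPs (n = 4), lung FAPs (n = 5) and MEFs (n = 4), where each point is a library, bars are means and values under 0.01 are drawn at 0.01. Hoxc10 stands at 31.9 CPM in muscle FAPs and 0 in lung FAPs, Tcf21 at 0.759 and 112, and Hspa1b at 4399 and 89.8.

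Muscle FAPs carried more matrix transcripts than lung FAPs. Col4a2, a chain of basement membrane collagen, stood at 3841 ± 534 CPM against 426 ± 147 (log2 fold change 3.17, SE 0.32, edgeR adjusted p = 2.15e-07). Col15a1, a collagen at the outer face of basement membranes, stood at 2827 ± 497 against 319 ± 141 CPM (3.14, SE 0.38, edgeR adjusted p = 1.28e-06). Of 32 matrix genes, 25 were higher, 1 was lower and 6 did not pass (camera adjusted p = 7.81e-08; adjusted p = 0.271 with an estimated correlation). Col6a3 (2.99) and Lama2 (2.03) were among the higher, and Fbln1 (−1.58) was the lower. Tenocyte markers moved with this list, with 8 of 8 higher and mean sums of 1779 CPM in muscle FAPs and 148 in lung FAPs, without overlap. Complement genes ran the other way, with 1 higher, 8 lower and 5 not passing of 14 (camera adjusted p = 0.0057; adjusted p = 0.264 with an estimated correlation). C4b stood at 173 ± 7.76 against 1128 ± 287 CPM (−2.71, SE 0.19, edgeR adjusted p = 7.14e-07), and Masp1 (0.90) was the higher gene.

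Secreted signals moved in both directions. Of 49 growth factors, 22 were higher in muscle FAPs, 17 were lower and 10 did not pass (camera adjusted p = 0.66; 17 higher and 21 lower with library size as the only scaling). Wnt2b, a WNT ligand of lung mesenchyme, stood at 3.35 ± 0.689 CPM against 100.5 ± 28.6 (−4.92, SE 0.25, edgeR adjusted p = 7.67e-09), and Apln, the ligand of the apelin receptor, at 0.655 ± 0.263 against 9.21 ± 6.100 (−3.82, SE 0.56, adjusted p = 3.38e-05). Bmp4 rose by 1.82, while Fgf10 (−2.003) and Figf (−2.54) fell. Of 18 antagonists of WNT, BMP and activin, 8 were higher, 5 lower and 5 did not pass (camera adjusted p = 0.402). Bmper, which binds BMPs outside the cell, stood at 407 ± 65.9 CPM against 23.5 ± 7.34 (4.10, SE 0.24, edgeR adjusted p = 1.88e-09). Wif1, a WNT inhibitor, stood at 11.4 ± 5.36 against 1.19 ± 0.833 (3.24, SE 0.57, edgeR adjusted p = 4.84e-05). Dkk3 fell by 2.66. Of 29 cytokines and chemokines, 12 were higher, 6 lower and 11 did not pass (camera adjusted p = 0.053; 0.0219 to 0.0389 without muscle FAP 5, lung FAP 2 or lung FAP 4). Il1b had 3 reads over all muscle FAPs against 15.99 ± 7.78 CPM, a ratio of 740.4 (95% interval 253 to 3592) with an edgeR adjusted p of 3.67e-08. Muscle FAP 5 held 2 of the 3 reads, and the fitted log2 fold change was −9.31, or −10.27 without it.

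Progenitor markers split between both kinds of FAP, with 5 higher in muscle FAPs, 5 lower and 5 not passing of 15 (camera adjusted p = 0.976). Procr, the endothelial protein C receptor, stood at 590.2 ± 133 CPM against 105 ± 61.3 (2.49, SE 0.40, edgeR adjusted p = 5.93e-05), and Gli1, a target of hedgehog signalling, at 21.2 ± 3.55 against 129 ± 19.6 (−2.61, SE 0.15, adjusted p = 3.30e-08). Of 27 adipogenic genes, 12 were higher, 9 lower and 6 did not pass (camera adjusted p = 0.325). Adipoq, the fat cell hormone adiponectin, stood at 0.192 ± 0.223 against 5.89 ± 6.19 CPM (−4.93, SE 0.92, edgeR adjusted p = 0.0014; −4.02 without lung FAP 1 and −5.89 without muscle FAP 5). Cd36, a fatty acid transporter, stood at 4.54 ± 2.45 against 60.4 ± 57.3 (−3.74, SE 0.82, edgeR adjusted p = 0.00286; −3.04 without lung FAP 2, −2.51 without lung FAP 2 and 3, and −1.47 with an adjusted p of 0.042 without lung FAP 2, 3 and 4). Lpl (1.68) and Cebpa (1.498) rose.

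Contractile and stress genes stood far apart between muscle FAPs and lung FAPs. Of 17 contractile and myofibroblast genes, 3 were higher in muscle FAPs, 11 lower and 3 did not pass (camera adjusted p = 0.00041; adjusted p = 0.174 with an estimated correlation). Actg2, a smooth muscle actin, stood at 0.102 ± 0.0511 CPM in muscle FAPs against 32.99 ± 24.5 in lung FAPs (−8.30, SE 0.59, edgeR adjusted p = 7.76e-06), and Cnn1, an actin-binding calponin, at 0.263 ± 0.0854 against 39.2 ± 30.97 (−7.21, SE 0.54, adjusted p = 8.68e-06; −6.62 without lung FAP 2). Acta2 fell by 6.39 and peaked at 887 CPM in lung FAP 2. Markers of pericytes and smooth muscle moved with this list, with 8 of 10 lower and sums of 92.9 to 101 CPM in muscle FAPs and 422 to 1443 in lung FAPs. Itga11 (2.33) and Fap (2.68) rose. Of 20 immediate-early and stress genes, 11 were higher in muscle FAPs, 1 was lower and 8 did not pass (camera adjusted p = 0.000183; adjusted p = 0.428 with an estimated correlation). Hspa1b, an inducible heat-shock protein 70, stood at 4399 ± 492 CPM against 89.8 ± 19.1 (5.61, SE 0.16, edgeR adjusted p = 2.29e-10), and Hsph1, its nucleotide exchange factor, at 3296 ± 444 against 90.3 ± 9.88 (5.18, SE 0.12, adjusted p = 3.40e-12). The group means of Fos did not differ (2535 and 2422 CPM), and Fosb (−1.88) was the lower gene. Lung FAPs were uneven in Fos, with 1119 and 1482 CPM in lung FAP 2 and 4 and 2716 to 3973 in the others. Muscle FAPs held 2085 to 2831 CPM. Of 30 cell cycle genes, 6 were higher, 7 lower and 17 did not pass (camera adjusted p = 0.63). Rrm2, a subunit of ribonucleotide reductase, stood at 6.701 ± 0.536 against 2.88 ± 0.762 CPM (1.21, SE 0.19, edgeR adjusted p = 4.77e-04). Mcm3, part of the replicative helicase, stood at 14.8 ± 1.97 against 8.18 ± 1.15 (0.85, SE 0.13, edgeR adjusted p = 9.79e-05).

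Markers of other cell types were measured in the same libraries. Lung epithelium markers were 0 higher and 10 lower in muscle FAPs, with 5 not passing of 15 (camera adjusted p = 0.000833; adjusted p = 0.428 with an estimated correlation). Scgb1a1, the main secretory protein of club cells, stood at 0.426 ± 0.574 CPM in muscle FAPs and 1053 ± 2249.7 in lung FAPs (−11.26, SE 1.81, edgeR adjusted p = 0.00435; −6.77 without lung FAP 3 and −12.79 without muscle FAP 4). Scgb3a2 had 1 read over all muscle FAPs against 54.1 ± 105 CPM, a ratio of 7476 (95% interval 1341 to 295307) with an edgeR adjusted p of 0.00339. Bpifa1 had 1 read against 32.2 ± 48.02 CPM, a ratio of 4466 (95% interval 801 to 176427) (edgeR adjusted p = 3.66e-04), and Bpifb1 none against 10.8 ± 16.7, at least 491-fold lower, and 164-fold without lung FAP 3 (adjusted p = 0.0413; 0.0570 to 0.134 without any one muscle FAP library, with no filter, in glmTreat or with both groups alone). These airway genes were high in lung FAP 3, at 241, 117 and 39.4 CPM for Scgb3a2, Bpifa1 and Bpifb1. The single reads of Scgb3a2 and Bpifa1 lay in muscle FAP 4. The edgeR log2 fold changes without lung FAP 3 were −9.44 for Scgb3a2 and −10.04 for Bpifa1. With limma-voom the adjusted p values of Scgb1a1, Scgb3a2 and Bpifa1 were 0.184, 0.179 and 0.0805.

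Blood cell markers were 0 higher, 21 lower and 3 not passing of 24 in muscle FAPs against lung FAPs (camera adjusted p = 9.55e-09; adjusted p = 0.11 with an estimated correlation). Lyz2, lysozyme of macrophages and alveolar cells, stood at 0.529 ± 0.306 CPM against 127 ± 269.7 (−7.91, SE 1.37, edgeR adjusted p = 0.0104), and at −3.58 (adjusted p = 9.31e-05) without lung FAP 3. With limma-voom its adjusted p was 0.195. Endothelial markers were 2 higher, 14 lower and 2 not passing of 18 (camera adjusted p = 0.000748; adjusted p = 0.49295 with an estimated correlation). Tek, an angiopoietin receptor, stood at 251 ± 35.8 against 185 ± 44.9 CPM (0.43, SE 0.18, edgeR adjusted p = 0.034; 0.0621 to 0.105 without any of 6 libraries in turn, 0.0813 under upper-quartile scaling, and 0.030 with an adjusted p of 0.882 under library size only), while Pecam1 fell by 5.46 (4.20 without lung FAP 2). Lung FAP 2 was highest among lung FAPs for 17 of 18 endothelial and 10 of 10 pericyte and smooth muscle markers, and held 129.6 CPM of Pecam1 against 4.39 to 40.9 in the others. Without it 1 endothelial marker was higher and 13 lower of 17, with a median of −3.78 against −5.45. Pericyte and smooth muscle markers were 1 higher, 8 lower and 1 not passing of 10 (camera adjusted p = 0.000315; adjusted p = 0.271 with an estimated correlation). Abcc9, a potassium channel subunit of pericytes, stood at 18.4 ± 1.999 against 263 ± 12.1 CPM (−3.84, SE 0.084, edgeR adjusted p = 4.80e-12). It was nearly level over the lung FAPs, at 248 to 278 CPM, and was at −3.81 without lung FAP 2. Cox4i2 of the same list stood at 77.7 CPM in lung FAP 2 and 3.81 to 11.2 in the others. The fall of Abcc9 therefore does not follow the pericyte markers that peaked in lung FAP 2. All 7 mesothelial markers were lower (camera adjusted p = 3.11e-05; adjusted p = 0.265 with an estimated correlation), Upk3b among them at 2.75 ± 3.01 against 269 ± 111 CPM (−6.63, SE 1.47, edgeR adjusted p = 1.31e-04).

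Tendon markers were higher in muscle FAPs, with all 8 tenocyte genes passing (camera adjusted p = 5.88e-05; adjusted p = 0.0141 with an estimated correlation). Thbs4, a matrix glycoprotein of tendon, stood at 1183 ± 332 CPM against 29.6 ± 19.2 (5.31, SE 0.66, edgeR adjusted p = 6.86e-06), and Tnmd at 51.9 against 0.718. Muscle fibre markers were 0 higher, 8 lower and 11 not passing of 19 (camera adjusted p = 0.292; 0.0405 without lung FAP 4), and Eno3, the muscle enolase, stood at 7.57 ± 1.27 against 9.201 ± 1.86 CPM (edgeR adjusted p = 0.366; −0.71 and 0.0303 under library size only). Markers of satellite cells and myoblasts were 4 higher, 1 lower and 5 not passing of 10 (camera adjusted p = 0.63), and Des, desmin, stood at 23.9 ± 4.02 against 95.8 ± 69.6 CPM (−2.01, SE 0.48, edgeR adjusted p = 0.00202). Schwann cell markers were 1 higher, 3 lower and 3 not passing of 7 (camera adjusted p = 0.63), with Cnp at 15.1 ± 3.04 against 28.7 ± 4.95 CPM (−0.94, SE 0.19, edgeR adjusted p = 1.87e-04). Of the red blood cell list 1 gene could be tested, Alas2, which stood at 0.247 ± 0.141 against 1.599 ± 2.25 CPM (−2.68, SE 0.99, edgeR adjusted p = 0.0385). Without lung FAP 4 it was at −1.35 (edgeR adjusted p = 0.196). Its adjusted p was 0.0535 to 0.1001 in edgeR without any one muscle FAP library, and 0.422 in limma-voom. The haemoglobin gene Beta-s, outside the list under that symbol and chosen after the results were seen, stood at 0.494 ± 0.470 against 17.7 ± 28.0 CPM. Its change was −5.16 (SE 1.70, edgeR adjusted p = 0.0476). None of 5 sex-linked genes passed (camera adjusted p = 0.971), Ddx3y among them at 225 ± 29.4 and 158 ± 29.6 CPM (edgeR adjusted p = 0.644, and 0.0181 with both groups alone). The shared fit takes its spread in part from MEFs, where Ddx3y ran from 0.0646 to 70.9 CPM. The lack of calls for these genes therefore decides little, while their values in single libraries say more. Every FAP library of both tissues held at most 0.589 CPM of Xist and at least 122 CPM of Ddx3y, the pattern of male cells.

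**Figure D3:**
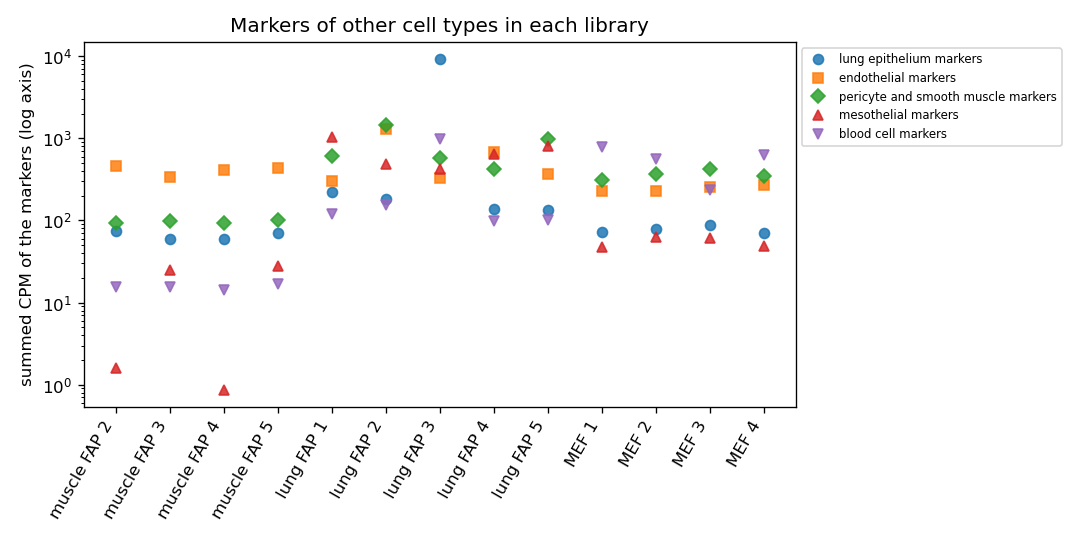
Summed CPM (log axis) of the markers of lung epithelium, endothelium, pericytes and smooth muscle, mesothelium and blood cells in each of 13 libraries, where each point is a list in a library. Epithelial sums reach 9249 CPM in a lung FAP library against 59.6 to 74.1 in muscle FAPs, and mesothelial sums stand at 427 to 1043 in lung FAPs against 0.861 to 27.9 in muscle FAPs.

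Over all genes, muscle FAPs against lung FAPs gave 3574 higher and 3850 lower genes in edgeR, and 7988 of 15412 did not pass. Of the passing genes, 1406 higher and 1890 lower genes changed by at least 2-fold. Tested against a 2-fold change with glmTreat, the smaller rises of Pdgfra and Mcm3 and the fall of Cnp had an adjusted p of 1, and Rrm2 one of 0.366. Among the passing genes, 2837 higher and 2786 lower ones showed no overlap of libraries between both groups. Chance alone gives 1.59% of all genes, while passing genes were picked by this same group difference. The direction counts depend on scaling. With library size as the only scaling the median log2 fold change of all genes shifted by −0.41, and 1730 genes were higher and 7455 lower, so that 18.8% of changed genes were higher against 48.1% with TMM. Adjusted over the list alone, the counts were 25 higher and 2 lower for matrix, 10 and 5 for the antagonists, 12 and 10 for adipogenic genes, 9 and 9 for Hox paralogs 1 to 8, 6 and 6 for the cell cycle, 12 and 1 for stress, 0 and 12 for epithelium, and unchanged in the other lists. Median, mean and camera differed in sign for progenitor markers (−0.14, 0.0043, up), growth factors (0.20, −0.048, up), adipogenic genes (0.49, −0.41, up), Hox paralogs 1 to 8 (−0.11, 0.17, down) and Schwann cell markers (0.23, 0.050, down). Under library size only the medians of the growth factors (−0.20), satellite cell markers (0.13 to −0.30), Schwann cell markers (−0.18) and sex-linked genes (−0.071) turned negative.

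Muscle FAPs differed from MEFs in matrix, cytokine and complement genes. Myoc, a secreted protein of the eye's drainage tissue and of muscle, stood at 2132 ± 395 CPM in muscle FAPs and 0.417 ± 0.419 in MEFs (log2 fold change 12.32, SE 0.89, edgeR adjusted p = 1.48e-08). Cilp, a matrix protein that binds TGF-beta, stood at 2133 ± 840.3 against 0.604 ± 0.442 CPM (11.79, SE 0.61, edgeR adjusted p = 9.18e-10). Vtn, vitronectin, stood at 205 ± 26.9 against 0.0726 ± 0.0446 (11.42, SE 0.29, edgeR adjusted p = 4.74e-07), and Col6a6 at 501 ± 79.3 against 0.197 ± 0.1198 (11.32, SE 0.45, adjusted p = 5.69e-09). Matrix genes were 24 higher, 4 lower and 4 not passing (camera adjusted p = 1.19e-05; adjusted p = 0.327 with an estimated correlation), with Col15a1 at 10.13 (SE 0.13, edgeR adjusted p = 5.33e-11) and Tnc at −5.58. Progenitor markers were 12 higher, 1 lower and 2 not passing (camera adjusted p = 0.000124; adjusted p = 0.156 with an estimated correlation). Pi16, a marker of adventitial fibroblast progenitors, stood at 1177 ± 162 against 1.74 ± 0.804 CPM (9.43, SE 0.40, edgeR adjusted p = 1.13e-10).

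Most cytokine and complement genes were higher in muscle FAPs than in MEFs. Ccl11, which attracts eosinophils, stood at 1174 ± 179 CPM against 0.4798 ± 0.0776 (log2 fold change 11.28, SE 0.15, edgeR adjusted p = 4.12e-14). Cytokines and chemokines were 21 higher, 3 lower and 5 not passing (camera adjusted p = 1.66e-05; adjusted p = 0.0626 with an estimated correlation), and Il6 stood at 822 against 0.887 CPM. Complement genes were 13 higher and 1 lower (camera adjusted p = 5.27e-06; adjusted p = 0.0626 with an estimated correlation), with C7, a part of the membrane attack complex, at 740.1 ± 177 against 0.927 ± 0.6001 CPM (9.68, SE 0.64, edgeR adjusted p = 2.01e-10). Growth factors were 25 higher, 19 lower and 5 not passing (camera adjusted p = 0.382). Bmp5 stood at 176 ± 24.4 against 1.03 ± 0.195 CPM (7.44, SE 0.16, edgeR adjusted p = 1.72e-10), while Igf2 (−4.90) and Bdnf (−7.02) fell. The antagonists were 11 higher, 5 lower and 2 not passing (camera adjusted p = 0.0455, and 0.0535 without muscle FAP 3; adjusted p = 0.324 with an estimated correlation). Grem1, a BMP antagonist, stood at 0.447 ± 0.328 against 181 ± 17.4 CPM (−8.62, SE 0.57, edgeR adjusted p = 9.83e-12).

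Proliferation and contractile genes were low in muscle FAPs against MEFs. Cell cycle genes were 1 higher, 27 lower and 2 not passing (camera adjusted p = 4.05e-06; adjusted p = 0.0607 with an estimated correlation), with Cdk1, the mitotic kinase, at 0.352 ± 0.149 against 16.1 ± 2.61 CPM (−5.48, SE 0.31, edgeR adjusted p = 4.59e-08). Contractile genes were 2 higher, 14 lower and 1 not passing (camera adjusted p = 0.000656; adjusted p = 0.216 with an estimated correlation), with Actg2 at 0.102 against 114 ± 41.7 CPM (−10.04, SE 0.39, edgeR adjusted p = 3.92e-07). Adipogenic genes were 14 higher, 7 lower and 6 not passing (camera adjusted p = 0.0387; adjusted p = 0.324 with an estimated correlation), with Apod, a lipocalin, at 865 ± 131 against 3.21 ± 0.538 CPM (8.10, SE 0.16, edgeR adjusted p = 5.05e-13) and Fasn at −3.22. All 20 stress genes were higher (camera adjusted p = 4.18e-09; adjusted p = 0.288 with an estimated correlation), with Hspa1a at 3256 ± 276 against 6.63 ± 1.701 CPM (8.97, SE 0.18, edgeR adjusted p = 2.30e-12). Limb factors were 5 higher, 8 lower and 3 not passing (camera adjusted p = 0.726), and Msx2 stood at 0.409 ± 0.127 against 18.3 ± 8.23 CPM (−5.44, SE 0.36, edgeR adjusted p = 5.60e-08). Genes of lung mesenchyme were 3 higher, 3 lower and 7 not passing (camera adjusted p = 0.964), and Inmt, a methyltransferase of lung, stood at 524 ± 131 against 1.09 ± 0.809 CPM (8.94, SE 0.60, edgeR adjusted p = 6.87e-10).

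Hox genes of paralogs 9 to 13 were 4 higher and 10 lower in muscle FAPs than in MEFs, with 2 not passing (camera adjusted p = 0.0717; 0.0455 without muscle FAP 4), and Hoxd13, of the distal limb, stood at 0.608 ± 0.183 against 28.1 ± 3.91 CPM (−5.497, SE 0.25, edgeR adjusted p = 5.38e-10). Paralogs 1 to 8 were 3 higher, 9 lower and 9 not passing (camera adjusted p = 0.316), with Hoxb8 at 0.243 ± 0.183 against 6.93 ± 1.45 CPM (−4.79, SE 0.73, edgeR adjusted p = 2.33e-05). Among the largest differences toward MEFs were genes of blood cells. Lcp1, an actin bundler of leukocytes, stood at 0.0292 ± 0.000478 against 52.4 ± 21.01 CPM (−10.62, SE 0.37, edgeR adjusted p = 1.07e-07). Its level in muscle FAPs lies near the floor of 0.0219 CPM, so this SD and SE do not cover its counting error. Lilrb4, an inhibitory receptor of myeloid cells, had 1 read over all muscle FAPs against 18.2 ± 9.28 CPM, a ratio of 2472 (95% interval 443 to 97660.5) (edgeR adjusted p = 8.83e-08), and Fcrls, of microglia and macrophages, 1 read against 11.03 ± 7.18 CPM, a ratio of 1517 (95% interval 272 to 59959) (adjusted p = 7.58e-08). Both reads lay in muscle FAP 3, and without that library muscle FAPs had no read of either gene. Blood cell markers were 1 higher, 15 lower and 8 not passing (camera adjusted p = 0.00105; adjusted p = 0.324 with an estimated correlation), with a median log2 difference of −5.25 at the bounds. Lyz2 stood at 0.529 against 208 ± 107 CPM (−8.59, SE 0.59, edgeR adjusted p = 0.00432), and C1qb at 0.0513 against 41.9.

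No other list of markers passed in camera for muscle FAPs against MEFs, though single markers differed widely. Adjusted p values and counts were 0.726 for muscle fibres (7 higher, 3 lower, 9 not passing), 0.106 for satellite cells (1, 7 and 2), 0.726 for epithelium (1, 3 and 11) and 0.803 for endothelium (4, 5 and 9). They were 0.726 for pericytes (2, 3 and 5), 0.106 for mesothelium (0, 3 and 4; 0.0438 without muscle FAP 5), 0.2 for tenocytes (5, 2 and 1), 0.726 for Schwann cells (2, 3 and 2) and 0.63 for sex-linked genes (1, 1 and 3). Tek stood at 251 against 3.95 ± 0.511 CPM (6.02, SE 0.14, edgeR adjusted p = 2.23e-12), Abcc9 at 18.4 against 1.04 ± 0.144 (4.17, SE 0.13, adjusted p = 5.68e-13) and Thbs4 at 1183 against 1.15 ± 0.287 (10.03, SE 0.27, adjusted p = 7.44e-08). Eno3 was lower than in MEFs (117 ± 49.2 CPM; −3.92, SE 0.34, edgeR adjusted p = 1.55e-08) and Cnp higher than in MEFs (8.29 ± 0.645 CPM; 0.89, SE 0.15, adjusted p = 1.75e-04, 0.0791 under library size only and 0.813 in glmTreat). Des (edgeR adjusted p = 0.602), Scgb1a1 (0.567), Alas2 (0.666) and Upk3b (0.0718; 0.0411 without muscle FAP 5, 0.0473 without muscle FAP 3, 0.0222 under library size only, 0.0059 in limma-voom) did not pass. Ddx3y, of the Y chromosome, stood at 225 against 38.2 ± 29.2 CPM (2.59, SE 2.18, edgeR adjusted p = 0.0238; 0.0504 to 0.0781 without MEF 3 or MEF 4, under library size only, in glmTreat or with both groups alone). MEF 2 held 0.0646 CPM of Ddx3y beside 88.5 of Xist, and MEF 4 held 38.0 beside 101. The difference in Ddx3y therefore depends in part on the sex of the cells in the MEF samples.

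Muscle FAPs against MEFs gave 5570 higher and 5756 lower genes in edgeR, of which 3939 and 3573 changed by at least 2-fold, and 5188 and 5582 showed no overlap of libraries (by chance 2.86% of all genes, passing or not). With library size as the only scaling the median shifted by −0.58, 3757 genes were higher and 8089 lower, and 31.7% of changed genes were higher against 49.2% with TMM. Under that scaling the median of the growth factors turned from 0.42 to −0.16. Adjusted over the list alone, adipogenic genes were 15 higher and 7 lower and epithelium 1 and 2, with the other lists unchanged. Median, mean and camera differed in sign for lung mesenchyme (−0.082, 0.38, up), epithelium (0.051, −0.47, down; median 0.0042 at the bounds), endothelium (−0.13, 0.17, up) and sex-linked genes (1.27, −0.11, up). The median of the cytokines was 3.80 over all tested members and 4.03 at the bounds, where members of at most 3 counts in both groups are left out.

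Lung FAPs differed from MEFs in positional genes and in genes of lung mesenchyme. Dcn, the proteoglycan decorin, stood at 13785 ± 3244 CPM in lung FAPs and 75.1 ± 17.1 in MEFs (log2 fold change 7.56, SE 0.23, edgeR adjusted p = 3.11e-12). Pi16 stood at 3196 ± 1037 against 1.74 (10.88, SE 0.46, edgeR adjusted p = 3.75e-11). Matrix genes were 19 higher, 10 lower and 3 not passing (camera adjusted p = 0.0555; 0.0490 without lung FAP 2 and 0.0201 without lung FAP 4), and progenitor markers 12 higher, 1 lower and 2 not passing (camera adjusted p = 0.000431; adjusted p = 0.178 with an estimated correlation). Genes of lung mesenchyme were 12 higher and 0 lower with 1 not passing (camera adjusted p = 0.000232; adjusted p = 0.307 with an estimated correlation), and Inmt stood at 2214 ± 281 CPM (11.03, SE 0.58, edgeR adjusted p = 1.39e-10). Limb factors were 2 higher and 14 lower (camera adjusted p = 0.0115; adjusted p = 0.249 with an estimated correlation), with Pitx1, a factor of hindlimb identity, at 0.131 ± 0.2597 against 14.6 ± 3.66 CPM (−6.68, SE 0.69, edgeR adjusted p = 3.75e-06; −9.59 without lung FAP 1). All 16 Hox genes of paralogs 9 to 13 were lower (camera adjusted p = 6.67e-09; adjusted p = 0.0174 with an estimated correlation; median −8.56 at the bounds). Hoxc10 had no count in lung FAPs against 13.2 ± 1.85 CPM, at least 744-fold lower (edgeR adjusted p = 2.57e-11). Paralogs 1 to 8 were 8 higher, 11 lower and 2 not passing (camera adjusted p = 0.772), with Hoxc8 at 0.0725 against 6.77 ± 0.187 CPM (−6.46, SE 0.43, edgeR adjusted p = 7.51e-08; −7.13 without lung FAP 5).

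Complement and chemokine genes were high in lung FAPs as well. Complement genes were 13 higher and 1 lower (camera adjusted p = 2.02e-06; adjusted p = 0.0469 with an estimated correlation), with C7 at 1945 ± 225 CPM against 0.927 in MEFs (11.08, SE 0.62, edgeR adjusted p = 6.80e-11). Cytokines and chemokines were 21 higher, 5 lower and 3 not passing (camera adjusted p = 0.000431; adjusted p = 0.112 with an estimated correlation), and Ccl19, which attracts T cells and dendritic cells, stood at 124 ± 28.8 against 0.0514 CPM (11.21, SE 0.25, edgeR adjusted p = 9.16e-11). Growth factors were 26 higher, 18 lower and 5 not passing (camera adjusted p = 0.272), with Rspo1, an amplifier of WNT signals, at 51.4 ± 19.5 against 0.516 ± 0.0701 CPM (6.67, SE 0.27, edgeR adjusted p = 2.36e-06). The antagonists were 10 higher, 4 lower and 4 not passing (camera adjusted p = 0.0949), with Grem1 at 0.131 ± 0.0287 CPM (−10.36, SE 0.13, edgeR adjusted p = 1.86e-12). Adipogenic genes were 19 higher, 5 lower and 3 not passing (camera adjusted p = 0.0141; adjusted p = 0.319 with an estimated correlation), with Adipoq at 7.36 (SE 0.66, edgeR adjusted p = 8.86e-05; 6.45 without lung FAP 1 and 10.76 without MEF 2).

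Cell cycle genes were 1 higher, 26 lower and 3 not passing in lung FAPs against MEFs (camera adjusted p = 4.6e-06; adjusted p = 0.0346 with an estimated correlation), with Rrm2 at 2.88 against 96.5 ± 31.1 CPM (−5.03, SE 0.31, edgeR adjusted p = 8.22e-11). Contractile genes were 2 higher, 12 lower and 3 not passing (camera adjusted p = 0.0325, and 0.0509 without lung FAP 3; adjusted p = 0.362 with an estimated correlation), with Lrrc15, a myofibroblast surface protein, at 0.398 ± 0.4101 against 41.8 ± 20.6 CPM (−6.66, SE 0.77, edgeR adjusted p = 2.08e-06). Stress genes were 18 higher, 1 lower and 1 not passing (camera adjusted p = 7.68e-06; adjusted p = 0.362 with an estimated correlation), with Fosb at 2129 ± 811 against 7.86 ± 3.16 CPM (8.12, SE 0.42, edgeR adjusted p = 6.26e-10) and Hsph1 the lower gene (−0.38). Slitrk5, a synaptic adhesion protein, had no count in lung FAPs against 14.3 ± 1.75 CPM (at least 801-fold, edgeR adjusted p = 2.63e-08), as did the histone gene Hist1h2ab against 12.05 ± 1.32 (at least 677-fold, adjusted p = 2.34e-09) and Dgkk, a diacylglycerol kinase, against 11.6 ± 6.77 (at least 652-fold, adjusted p = 1.09e-05).

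The largest differences of lung FAPs from MEFs toward lung were surfactant and secretory genes of lung epithelium. Sftpa1 stood at 125 ± 278 CPM in lung FAPs against no count in MEFs, at least 7464-fold, and at least 71.4-fold without lung FAP 3 (edgeR adjusted p = 0.0288; 0.0502 to 0.106 without MEF libraries, with both groups alone or in glmTreat). Sftpc, the marker of alveolar type 2 cells, stood at 433 ± 965 against 0.0763 ± 0.0828 CPM (12.502, SE 2.14, edgeR adjusted p = 0.00968; 4.38 without lung FAP 3, 13.45 without MEF 1). Scgb1a1 rose by 13.68 (SE 1.64, edgeR adjusted p = 0.00141; 9.19 without lung FAP 3, 15.02 without MEF 1), and Scgb3a1 stood at 28.6 ± 51.8 CPM against no count, at least 1700.0-fold (adjusted p = 0.00328) and at least 327-fold without lung FAP 3. Lung FAP 3 held 623 CPM of Sftpa1, 2159 of Sftpc, 5077 of Scgb1a1 and 121 of Scgb3a1, while the other lung FAPs held 0.0895 to 2.86, 1.02 to 2.38, 12.6 to 84.0 and 1.45 to 12.2. With limma-voom the adjusted p was 0.165 for Sftpa1, 0.306 for Sftpc and 0.165 for Scgb1a1. Without MEF 2 and 4 that of Sftpc in edgeR was 0.0914. Epithelium markers as a list were 10 higher, 0 lower and 5 not passing (camera adjusted p = 0.0861).

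Endothelial markers were 15 higher, 2 lower and 1 not passing in lung FAPs against MEFs (camera adjusted p = 0.011; adjusted p = 0.617 with an estimated correlation), with Tek at 5.58 (SE 0.17, edgeR adjusted p = 3.22e-12). Camera adjusted p values and counts of the other lists were 0.863 for blood cells (9 higher, 9 lower, 6 not passing), 0.169 for pericytes (6, 1 and 3), 0.0555 for mesothelium (7, 0 and 0) and 0.696 for tenocytes (2, 4 and 2). They were 0.272 for muscle fibres (13, 2 and 4), 0.0949 for satellite cells (2, 6 and 2), 0.91 for Schwann cells (2, 2 and 3) and 0.565 for sex-linked genes (1, 1 and 3). Abcc9 rose by 8.01 (SE 0.11, edgeR adjusted p = 4.01e-15), Upk3b by 4.88 (SE 0.38, adjusted p = 2.33e-04), Thbs4 by 4.72 (SE 0.65, adjusted p = 1.39e-05), Cnp by 1.83 (SE 0.14, adjusted p = 6.99e-08) and Des by 1.75 (SE 0.47, adjusted p = 0.00235). Eno3 changed by −3.63 (SE 0.34, edgeR adjusted p = 1.10e-08). Lyz2 did not differ (edgeR adjusted p = 0.672), though without lung FAP 3 it was at −5.01 with an adjusted p of 2.82e-07, and 0.0244 in limma-voom. Alas2 rose by 3.20 (SE 0.998, edgeR adjusted p = 0.0107; 1.86 and 0.0584 without lung FAP 4, 3.98 without MEF 4, and 0.0989 in limma-voom), and Ddx3y by 2.09 (SE 2.19, adjusted p = 0.0483; 0.0514 to 0.187 under 15 of the alternatives). As for muscle FAPs, the rise of Ddx3y depends in part on the sex of the cells in the MEF samples.

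Lung FAPs against MEFs gave 5825 higher and 5639 lower genes in edgeR, of which 4191 and 3307 changed by at least 2-fold, and 4819 and 5141 showed no overlap of libraries (by chance 1.59% of all genes, passing or not). With library size as the only scaling the median shifted by −0.17, with 5217 higher and 6326 lower genes. Adjusted over the list alone, progenitor markers were 12 higher and 2 lower, growth factors 26 and 19, cytokines 21 and 6, and sex-linked genes 0 and 1, with the others unchanged. Median, mean and camera differed in sign for blood cells (−0.092, 0.31, down), Schwann cells (0.50, −0.81, up) and sex-linked genes (1.56, −0.29, up).

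Among 96 tested genes of secreted signals, 29 were higher in muscle FAPs than in both lung FAPs and MEFs, and 10 were lower than in both. Cxcl14, a chemokine of resting fibroblasts, stood at 1767 ± 381 CPM in muscle FAPs, 111 ± 50.6 in lung FAPs and 39.3 ± 7.06 in MEFs, with log2 fold changes of 3.99 (SE 0.35, edgeR adjusted p = 1.61e-07) and 5.52 (SE 0.21, adjusted p = 4.37e-09). Bmper stood at 407, 23.5 and 34.4 ± 2.14 CPM (3.59 against MEFs, SE 0.13, edgeR adjusted p = 1.18e-09). Bmp2, a ligand that holds back myogenic differentiation in culture, stood at 157 ± 17.9, 18.8 ± 7.43 and 5.01 ± 0.454 CPM, with 3.05 (SE 0.29, edgeR adjusted p = 2.08e-07) and 4.997 (SE 0.10, adjusted p = 1.14e-09). Wif1 stood at 11.4, 1.19 and 1.19 ± 0.315 CPM (3.29 against MEFs, SE 0.42, edgeR adjusted p = 3.03e-05). Cxcl5, an attractant of neutrophils, stood at 30.97 ± 9.97, 4.07 ± 2.39 and 1.65 ± 1.16 CPM, with 2.92 (SE 0.46, edgeR adjusted p = 2.46e-04) and 4.25 (SE 0.53, adjusted p = 1.18e-05). Cxcl9, induced by interferon gamma, stood at 57.9 ± 58.6, 2.55 ± 1.52 and 0.0735 CPM, with 4.49 (SE 0.70, edgeR adjusted p = 5.88e-05) and 9.59 (SE 0.63, adjusted p = 9.59e-07), and with 3.48 and 8.56 without muscle FAP 5.

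**Figure D4:**
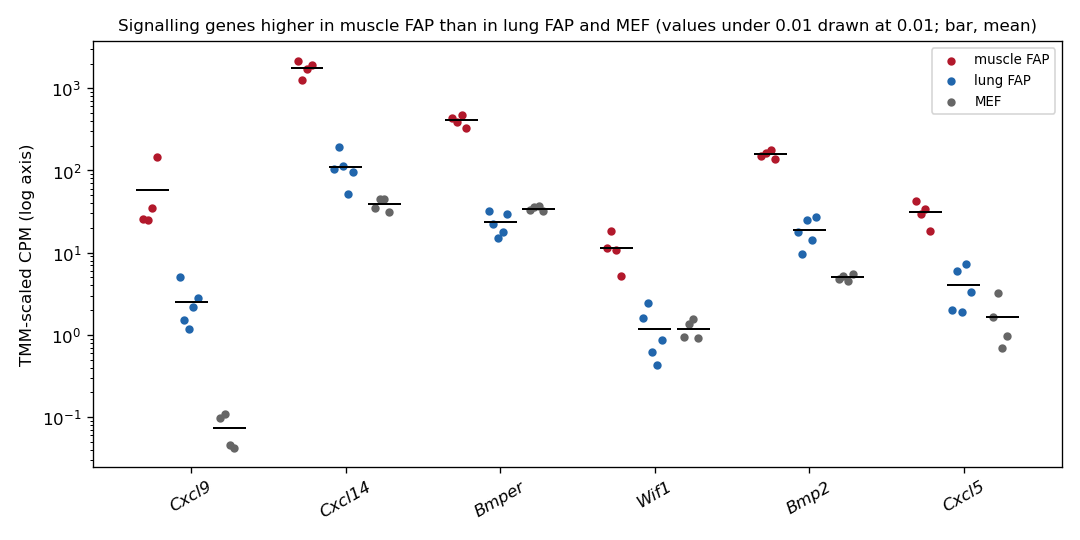
TMM-scaled CPM (log axis) of the 6 signalling genes highest in muscle FAPs (n = 4) against both lung FAPs (n = 5) and MEFs (n = 4), where each point is a library and bars are means. Cxcl14 stands at 1767, 111 and 39.3 CPM and Bmper at 407, 23.5 and 34.4.

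The signals higher in muscle FAPs than in both other groups were 12 of 49 growth factors (among them Bmp2, Bmp4, Bmp5, Bmp6, Fgf7, Fgf18, Tgfb2, Vegfa and Wnt11), 6 of 18 antagonists (Bmper, Chrd, Fst, Sfrp2, Sfrp5 and Wif1) and 11 of 29 cytokines and chemokines (Ccl11, Csf1, Cxcl1, Cxcl2, Cxcl5, Cxcl9, Cxcl10, Cxcl14, Il15, Lif and Tslp). The lower signals were 8 growth factors (Apln, Bdnf, Pdgfa, Rspo2, Wnt2b, Wnt4, Wnt5a and Wnt9a) and 2 antagonists (Fstl3 among them). Fst, which binds activin and myostatin, stood at 275 CPM in muscle FAPs, 91.4 in lung FAPs and 59.00 in MEFs, and Lif, a cytokine that drives myoblast growth, at 157, 59.97 and 21.9. Igf1 did not differ between both kinds of FAP (241 and 201 CPM). With library size as the only scaling 24 signals were higher than in both and 15 lower. Over all genes 2001 were higher and 1924 lower in muscle FAPs than in both groups. With library size as the only scaling the genes higher in muscle FAP than in both lung FAP and MEF were 881 and the genes lower in muscle FAP than in both lung FAP and MEF were 4789. With glmTreat against a 2-fold change they were 416 and 520. Both comparisons share the muscle libraries. Independent comparisons would give 1292 and 1438 such genes and 20 simulations without differences gave a mean of 0. Comparisons that used separate pairs of muscle FAP libraries gave 1201 to 1491 higher and 902 to 1160 lower genes. These splits used fewer libraries in each comparison, and no independent value was computed for them. They cannot be set against 1292 and 1438, which come from all libraries.

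All 82 genes taken by the rule lie in GENCODE M21 on GRCm38, and the deposited table gives no positions of its own. Hoxc10 lies on chromosome 15 at 102966796 to 102971893 (+), and Hoxa10 (52231197 to 52240854, −) and Hoxa9 (52223100 to 52231089, −) lie side by side on chromosome 6. Tbx15 lies on chromosome 3 at 99240381 to 99354259 (+), Tcf21 on chromosome 10 at 22817281 to 22820174 (−) and Npnt on chromosome 3 at 132881745 to 132950291 (−). Bmper lies on chromosome 9 at 23223076 to 23485200 (+), Cxcl14 on chromosome 13 at 56288643 to 56296551 (−), Bmp2 on chromosome 2 at 133552159 to 133562885 (+) and Pdgfra on chromosome 5 at 75152292 to 75198215 (+). Hspa1b (34956436 to 34959238, −) and Hspa1a (34969190 to 34972156, −) lie side by side on chromosome 17 and share 62.3% and 66.3% of their stretches of 50 bases, so their reads cannot be told apart with certainty. The same holds, among others, for Ccl19 (59.1% shared with Gm2564), Hist1h2ab (58.0%), Bmp5 (48.5% with Gm26903), Lilrb4 (43.5%), C4b (35.2% with C4a), Lyz2 (15.4% with Lyz1), Lcp1 (14.4%), Alas2 (13.8%, overlapping Apex2) and Ly6a (10.04% with Ly6c1). The levels of the 12 such genes that share at least 10% of such stretches are uncertain to that extent. Exons of 22 of the 82 genes, Hoxc10 among them, are overlapped by another gene.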

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

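Of the tests in this part, those on immediate-early genes, on the isolation ratio, on endothelial markers in lung FAP 3 and on epithelial markers in lung FAP 3 were chosen only after the result was seen. The SE of a median in this part is taken over the genes of a list, as if they were independent. It does not measure the spread between libraries. Of 236 groups of values, 31 held a single library far from the others of its group by Dixon's test, and chance flags about 1 in 20 groups of normally distributed values. They fell on lung FAP 3 in 8 cases, muscle FAP 4 in 5, lung FAP 2, muscle FAP 5 and MEF 2 in 3 each, lung FAP 1, lung FAP 4 and muscle FAP 3 in 2 each, and muscle FAP 2, MEF 3 and MEF 4 in 1 each. A gene with reads in only 1 library of a group is always flagged, as were Bpifa1 and Scgb3a2 in muscle FAP 4. The 31 cases can therefore not be set against the rate of 1 in 20.

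Markers of other cell types set lung FAP 3 apart, with values far above those of the other lung FAPs for Scgb1a1 (5077 against 12.6 to 84.0 CPM), Sftpc (2159 against 1.02 to 2.38), Sftpa1 (623 against 0.0895 to 2.86), Lyz2 (609 against 5.10 to 7.38), Scgb3a2 (241 against 1.45 to 14.99), Scgb3a1 (121 against 1.45 to 12.2), Bpifa1 (117 against 2.54 to 21.6) and Bpifb1 (39.4 against 0.165 to 11.5). Epithelial cells or their RNA in that sample are a candidate explanation that these genes raised themselves, and of the list of epithelial markers fixed before the data were examined 19 of 20 were highest in lung FAP 3, or 15 of 16 without the genes just named. A lower share of the main cell type, which could raise all other cell types at once, is argued against by the median log2 ratio of endothelial markers in lung FAP 3 of −2.56 (SE 0.35), beside 5.09 (SE 0.89) for epithelial and 0.58 (SE 0.46) for blood cell markers; lung FAP 2 was highest for 17 of 18 endothelial markers, and without it the medians were −1.28 (SE 0.23), 5.15 (SE 0.89) and 0.84 (SE 0.44). Cells confined to lung FAP 2 and 3 are argued against as the cause of most genes lower in muscle FAPs, since 3524 genes were called lower without both libraries, 3325 of them among the 3850, while cells present in every lung library were not tested. No sort or gate is given for the lung samples, so no biological explanation was tested.

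Heat-shock genes stood higher in muscle FAPs than in lung FAPs, with 21 of 23 targets higher and a median log2 fold change of 2.25 (SE 0.44), in libraries that also differed without overlap in ribosomal Rn45s (4884 to 7529 against 2375 to 3916 CPM) and in the share of the 10 highest genes (at least 16.8% against at most 14.5%), a source not tested. A handling stress that raises immediate-early genes together with heat-shock genes can be neither held nor excluded, since the immediate-early members had a median of 0.398 (SE 0.27; 7 higher and 1 lower of 16), and the same holds for stress of the endoplasmic reticulum, with a median of 0.450 (SE 0.17). Both labels were set to undecided after the values were seen, by asking for a distance of 2 SE from the bound. Genes of a list can move together, so these SEs over genes are likely too small. A step of the isolation that differed between muscle and lung may be at work, as the lowest muscle FAP library held 5.02 times the heat-shock sum of the highest lung FAP library, but tissue and isolation cannot be separated in this design. In lung FAPs against MEFs the immediate-early median was 4.08, while the heat-shock median was −0.48. Egr1 stood at 800 and 989 CPM in lung FAP 2 and 4 and at 2123 to 2811 in the other lung FAPs, and Fos was split alike. The immediate-early median of 0.398 therefore averages over unlike lung libraries.

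Blood cell genes stood in MEFs, where Lyz2 reached 327 CPM in MEF 1. Macrophages in the MEF samples, fewer in MEF 3, are a candidate explanation, since 17 of 17 macrophage genes were lowest in MEF 3, with sums of 422, 274, 111 and 370.0 CPM in MEF 1 to 4. Of the 29 blood cell markers fixed before the data were examined, 17 were lowest in MEF 3. Equal expression by the fibroblasts of every sample is argued against by the median ratio of MEF 3 to the other MEFs. Over 16 of the macrophage genes it was 0.292, where 10000 random lists gave 0.871 to 1.16. The design holds no group that tests a biological explanation.

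The other single-library values are given without explanation. In lung FAPs they were Adipoq in lung FAP 1 at 16.9 (others 2.83 to 3.46) and Pitx1 at 0.595 (others 0 to 0.0329). Lung FAP 2 held Bmp5 at 127 (others 47.3 to 65.3), Vtn at 28.1 (others 3.72 to 6.68) and Cnp at 19.98 (others 29.9 to 32.3), and lung FAP 4 held Ccl11 at 618 (others 391 to 449.9) and Col4a2 at 174 (others 441 to 533). In muscle FAP 4 they were Shox2 at 25.2 (others 14.3 to 15.5), Sftpc at 0.660 (others 0 to 0.0883), Sftpa1 at 0.0861, and Bpifa1 and Scgb3a2 at 0.0287 each (others 0). Muscle FAP 5 held Cxcl9 at 146 (others 25.3 to 35.1), Ly6a at 1008 (others 677 to 717) and Lyz2 at 0.983 (others 0.319 to 0.431). Muscle FAP 3 held Fcrls and Lilrb4 at 0.0294 each (others 0), and muscle FAP 2 Scgb3a1 at 0.116 (others 0). In MEFs they were Apln in MEF 2 at 26.5 (others 20.2 to 20.7), Cdk1 in MEF 2 at 20.03 (others 14.4 to 15.2), Adipoq in MEF 2 at 0.129 (others 0), Alas2 in MEF 4 at 0.395 (others 0.0925 to 0.108), and Il1b in MEF 3 at 0 (others 0.0208 to 0.0246).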

How the results depend on the processing

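The alternatives that scale by library size only or leave out lung FAP 2 and 3, lung FAP 2, 3 and 4, or MEF 2 and 4 were chosen only after the results were seen. No called list and no named gene was called in the opposite direction under any alternative. Over all genes, 3 and 83 were called in the opposite direction under library size only, for muscle FAP against lung FAP and against MEF. Without lung FAP 2, 3 and 4 it was 1 gene, for muscle FAP against lung FAP. Of the counts of genes under all alternatives, 162 stayed within 1.5-fold and 12 moved. Of the values of named genes under all alternatives, 2435 kept their call, 11 gained one and 76 lost one, and of the values of lists, 851 kept it, 29 gained and 32 lost one. Most alternatives that ended or gave a call of a named gene stand beside its result in the report. Depth of 28636183 to 44699463 counts limits genes near 3 counts over a group, where folds are bounds. The strict filter tests fewer genes (11348) and no filter more (19742), so genes outside them have no value there.

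Under glmTreat against a fold of 2 the counts of genes were 732 higher and 1202 lower for muscle FAP against lung FAP, 3147 and 2745 for muscle FAP against MEF and 3413 and 2531 for lung FAP against MEF. The genes higher in muscle FAP than in both lung FAP and MEF were 416, and the genes lower in muscle FAP than in both lung FAP and MEF were 520. This test asks for a larger change by construction. With library size only they were 1730 higher and 7455 lower for muscle FAP against lung FAP, and 881 and 4789 for muscle FAP against both. That scaling leaves out the composition factors, whose group means were 0.797, 1.06 and 1.17. Lists called fell to 2, 0 and 3 in the comparisons with the correlation estimated, from 13, 10 and 11, and rose to 18 and 19 for both comparisons with MEFs in fry. The cause was not tested.

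Leaving out 1 library at a time gave 3047 to 3635 higher and 3308 to 3831 lower genes for muscle FAP against lung FAP, 5176 to 5383 and 5531 to 5679 for muscle FAP against MEF, and 5576 to 5816 and 5382 to 5778 for lung FAP against MEF. The DESeq2 test gave 3768 and 4004 for muscle FAP against lung FAP, and limma-voom 3987 and 4079. Without lung FAP 2 and 3 the same counts were 3430 and 3524, of which 3100 and 3325 were shared with all libraries. With the replicate number as a block they were 3352 and 3453, 5263 and 5554, 5535 and 5586 in the order of the comparisons. The block ended the edgeR calls of Alas2 (adjusted p = 0.0627), Tek (0.0824) and Lyz2 (0.0555) for muscle FAP against lung FAP and of Ddx3y against MEFs (0.0545 and 0.0791), and the camera call of the antagonists (0.0584), and gave the cytokines one (0.0323). In the pairing check, libraries of equal number in different groups had correlations of −0.0483 to 0.0613 after removal of group means in 11 pairs, 0 of them over 0.1, and in 4 of the 11 pairs the best partner had the same number, so the numbers were not read as pairs.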

Other observations

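The genes in this part were chosen only after the results were seen, while the splits of libraries at its end were set before the data were examined. Muscle FAPs carried both parts of the receptor for glial cell line-derived neurotrophic factor, which guides and sustains motor neurons and enteric nerves. Ret, the signalling kinase, stood at 222 ± 65.03 CPM in muscle FAPs against 3.04 ± 2.38 in lung FAPs (6.18, SE 0.57, edgeR adjusted p = 1.11e-06) and 9.15 in MEFs. Gfra1, which binds the ligand, stood at 134 ± 21.4 against 1.89 ± 0.436 CPM (6.14, SE 0.18, edgeR adjusted p = 4.80e-12) and 27.8 in MEFs. The ligand Gdnf stood at 6.51 ± 4.45, 0.789 and 6.22 CPM. Other chaperone genes were higher in muscle FAPs as well, Hspa8 at 12543 ± 1985 against 2498 ± 492 CPM (edgeR adjusted p = 3.96e-08) and Hsp90aa1 at 6314 ± 859 against 597 ± 75.7 (adjusted p = 1.07e-09).

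Some genes differed widely among the libraries of a group. In muscle FAP 2, 3, 4 and 5, Wt1, a factor of mesothelium, stood at 0.755, 14.2, 0.402 and 11.8 CPM, Upk3b at 0.232, 5.21, 0.0574 and 5.48, Hoxb9 at 0.784, 3.53, 0.230 and 3.61, and Sfrp4, a WNT antagonist, at 88.2, 230.1, 70.6 and 216. Muscle FAP 3 and 5 stood above muscle FAP 2 and 4 for each of these genes, and for Tcf21, Cilp, Rspo1 and Pitx1. The group means of such genes cover unlike levels. Other genes, Cxcl9 and Shox2 among them, were not split this way. In MEF 1 to 4, Xist, expressed from the inactive X chromosome, stood at 0.123, 88.5, 0.0231 and 101 CPM, Ddx3y at 70.9, 0.0646, 43.8 and 38.0, and Kdm5d, also of the Y chromosome, at 15.1, 0, 11.002 and 7.31. Spp1, osteopontin, stood at 586, 312, 107 and 763 CPM in MEF 1 to 4 and at 85.1 in lung FAP 2. In lung FAP 1 to 5, Myh4, a myosin of fast muscle fibres, stood at 7.68, 0.0283, 5.49, 0 and 14.4 CPM, Tnnc2 at 8.33, 0.452, 5.66, 0.0329 and 8.44, and Pvalb at 8.33, 0.226, 5.10, 0 and 8.92. Lung FAP 2 and 4 were thus lowest for each of these fibre genes, as they were for Fos and Egr1. The haemoglobin gene Beta-s stood at 19.9 CPM in lung FAP 2 and 65.6 in lung FAP 4, and at no more than 1.61 in any other library.

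The libraries were also split in ways other than their groups. For muscle FAP against lung FAP, 1 of 100 splits, the real one, reached its 7424 changed genes, and the highest other split gave 4208. For muscle FAP against MEF it was 1 of 35 with 11326 genes against 0, for lung FAP against MEF 1 of 100 with 11464 against 7878, and for genes changed against both groups 1 of 100 with 3925 against 0. The real split was the largest each time. Most other splits mix the groups and gave 0 or 1 gene, so the counts say little beyond that, and whether chance can be excluded was not settled by them.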
